A study of Escherichia coli K-12 with 2 samples.

How the data were processed

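RNA that co-purified with MS2-tagged spacers of the Escherichia coli metZWV tRNA operon was measured by sequencing in 2 libraries of strain MG1655. The libraries came from the tagged baits and from the same baits without the tag, 1 each. In MS2-affinity purification coupled with RNA sequencing, the bait RNA carries a hairpin that is bound by the MS2 coat protein. The coat protein is fused to maltose-binding protein and held on amylose resin, so RNAs that stay attached to the bait are eluted with it. Per the labels' protocols, bait expression was induced for 10 min with 0.1% arabinose in 50 mL LB cultures harvested at an OD600 of 0.5 and of 1, the lysate was passed over 200 pmol of coat protein, and RNA was eluted with 15 mM maltose. The labels give each library as 2 baits (ITSmetZW and ITSmetWV) and 2 growth phases together, so neither the bait nor the growth phase can be separated. Libraries were made with a small-RNA kit after DNase treatment, per the labels' protocols. No molecular identifiers are mentioned there.

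The deposited table gives, per the file headers, read counts per gene or intergenic region for each library, a normalized value and the ratio of tagged to untagged. The authors' read counts are whole numbers with no normalization. Their normalized value was taken to be the read count divided by 1 total per library. These totals, the summed reads over the summed normalized values, were 2025738 for the tagged and 2093320 for the untagged library. Ratios recomputed with them equal the deposited ones within a relative difference of 8.7e-08. A factor per feature shared by both libraries would not show in such ratios. Each deposited ratio equals the quotient of the 2 normalized values within a relative difference of 8.2e-06. Bowtie is named in the submitters' processing notes. Its version and role, the genome build, the annotation and the counting rule, including whether strand was used, are not given in the sources used here. The table lists only features with at least 1 read in both libraries: none of its 7039 features (4223 genes and 2816 intergenic regions) has a count of 0. RNAs bound by the bait and without a read in the control are therefore not analysed here. The listed reads sum to 868608 in the tagged and 1315642 in the untagged library, equal to 42.9% and 62.8% of the totals. What the other reads were is not stated. These sums can count a read more than once. For example, yadH and the yadH–yadI region have 10218 and 10192 tagged reads, and 20 such pairs of a region and an adjoining gene differed by at most 10% in both libraries.

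Read counts were divided by the authors' library totals, and the ratio of tagged to untagged was taken without a pseudocount. The plan fixed before the data were examined took library shares and named the column total as their denominator. After the table was seen to hold only part of each library, the authors' totals were put in its place and the column total became an alternative. This change was made with the ratios already visible, and it lowers every log2 ratio by 0.55. Each ratio has an exact (Clopper-Pearson) 95% binomial interval given the summed reads. Intervals cover counting error only, since PCR reads without molecular identifiers are not independent molecules. With 1 library per group there is no replicate, so no p-value or test between the conditions is given, and features are described by fixed rules of size. A filter of at least 10 reads over both libraries kept 5203 features (73.9%). A listed RNA counted as higher when its ratio was 2 or more with a lower bound above 1, and as lower at 0.5 or less with an upper bound below 1.

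The 12 gene lists were fixed before the data were examined, as were the settings and the rule for named features: metZ, metW, metV and metY; RyhB, RybB and MicF; the 12 Hfq sRNAs with the highest level; the RNAs of other protein complexes; the 10 largest and 5 smallest ratios among features with at least 100 reads over both libraries; and up to 3 members of every other list by level. Features named outside this rule are identified where they appear. The interval of a list median comes from 1000 Poisson resamples of its counts. Its percentile is the share of 10000 random lists of the same size, matched in 10 bins of level, with a lower median, and describes these 2 libraries. Random lists draw features singly, so percentiles may be too extreme for lists whose members lie side by side or share sequence. For medians over or among neighbouring genes, the interval comes from 1000 resamples of the genes, taken as independent, and not from counting error. Of the 4223 gene names, 3844 matched a symbol and 4060 a symbol or 1 synonym in a RefSeq gene table of MG1655 (assembly ASM584v2). That table was used for locus tags, neighbours and gene lengths. No coordinates are given because the build behind the table is not stated. The name ryeB is an older name of SdsR and was found under sdsR. Copies of rRNA and tRNA genes, metZ, metW, metV and metY among them, share near-identical sequence, so values of single copies are uncertain.

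On simulated Poisson counts for the tagged against untagged comparison, with 200 features changed 8-fold, 96.5% of the intervals over 5230 features held the true ratio. Of the raised features 96% passed 4-fold, and of the unchanged ones 0.298%. The simulated counts held no spread between purifications. These shares are therefore not error rates of the 4-fold rule in the real libraries. Of 400 random lists, drawn from all these features with the changed ones included, 50 fell below the 5th or above the 95th percentile. This is more than exact percentiles would give on average, an excess that was not tested against sampling variation. Among the first 100 lists 20 fell outside these percentiles, and the draw was enlarged to 400 after a share this high had been seen. Percentiles near 5 or 95 are therefore approximate. Alternatives were 6 other scalings (the column total, that total without bait tRNA genes or without tRNA and rRNA, unscaled reads, DESeq2 1.42.0 size factors and edgeR 4.0.16 TMM factors, the last as scaling only), a pseudocount of 5, filters of 50 reads and of none, other fold thresholds and other random lists. Leaving out a replicate was not possible. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and R 4.3.3.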

Results

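The series asked which small RNAs (sRNAs) bind the spacers of the metZWV operon, ITSmetZW between metZ and metW and ITSmetWV between metW and metV. These 3 genes encode initiator methionine tRNA. RNA retained on the MS2 coat protein column was compared between cells that made the MS2-tagged spacers and cells that made them untagged, with 1 library per group. The authors' library totals, as recovered from their normalized values, were 2025738 reads for the tagged and 2093320 reads for the untagged bait. The median listed feature had 15 and 12 reads, so intervals are narrow for abundant RNAs and wide for most others. All ratios are tagged over untagged library shares with exact 95% counting intervals. None has a replicate check, and the spread between purifications is unknown.

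The spacers themselves were among the RNAs with the highest ratios, whereas the tRNA genes beside them were not. The metW–metV spacer had 80 tagged and 3 untagged reads, a ratio of 27.6 (95% interval 9.10 to 136.4). The metZ–metW spacer had 69 and 5 reads, a ratio of 14.3 (5.82 to 45.3). These regions were picked from the labels after their values were seen, and together they gave a ratio of 19.2 (9.52 to 45.4). The flanks mltA–metZ (134 and 24 reads) and metV–amiC (13 and 4 reads), also chosen afterwards, had ratios of 5.77 (3.72 to 9.32) and 3.36 (1.04 to 14.1). The tRNA genes metW (locus b2815) and metV (b2816) had ratios of 2.39 (1.64 to 3.54) and 2.20 (1.53 to 3.22). For metZ (b2814) the ratio was 1.06 (0.682 to 1.64), an interval that includes 1. The 3 genes summed to 236 tagged and 130 untagged reads, a ratio of 1.88 (1.51 to 2.34). They are called bait tRNA genes here, although the labels give the spacers between them as the baits. The initiator tRNA gene outside the operon, metY (b3171), was lower, at 0.513 (0.375 to 0.695).

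Among sRNAs that act with the RNA chaperone Hfq, MicF, CyaR and RybB had the highest ratios, though RybB had few reads in the tagged library. MicF (b4439), which represses the porin OmpF, had 15555 tagged and 476 untagged reads, a ratio of 33.8 (30.8 to 37.1). CyaR (b4438), whose transcription is activated by cAMP-CRP, was the most abundant listed sRNA in the tagged library with 20965 reads against 1787, a ratio of 12.1 (11.6 to 12.7). RybB (b4417), an sRNA of the envelope stress response, had 356 and 67 reads and a ratio of 5.49 (4.22 to 7.24). ArcZ (b4450) followed at 2.60 (2.46 to 2.75), but arcB, a gene it overlaps that was picked after its values were seen, had nearly the same reads (4585 and 1809, against 4411 and 1755 for ArcZ). RyhB (b4451), the sRNA of iron limitation, had 2 tagged and 5 untagged reads. Its ratio of 0.413 (0.0394 to 2.52) allows no direction at this depth.

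Of the 29 listed Hfq sRNA names, 23 had at least 10 reads. MicF, CyaR, RybB and ArcZ were the 4 that were at least 2-fold higher. Another 8 were at least 2-fold lower and 11 were neither. By the same rule, 26.6% of all 5203 features were higher and 14.9% lower, so 4 of 23 is no excess over all features. With each library divided by its listed reads instead, 7 were at least 2-fold higher. McaS had a ratio of 1.89 (1.68 to 2.12), Spot 42 (spf) 1.83 (1.66 to 2.02), SgrS 1.498 (1.29 to 1.75) and GcvB 1.34 (1.28 to 1.41). RprA was at 1.11 (0.924 to 1.33). FnrS and ChiX had ratios of 0.683 (0.607 to 0.767) and 0.663 (0.550 to 0.796). GadY was at 0.461 (0.408 to 0.520). MicA, which like RybB belongs to the envelope stress response, had a ratio of 0.193 (0.147 to 0.250). The list median on the log2 scale was -0.55 (-0.72 to -0.07), which moved to 0.00 when each library was divided by its listed reads. Only 1.21% of random lists matched on level had a lower median, and their typical median was 0.34.

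**Figure D1:**
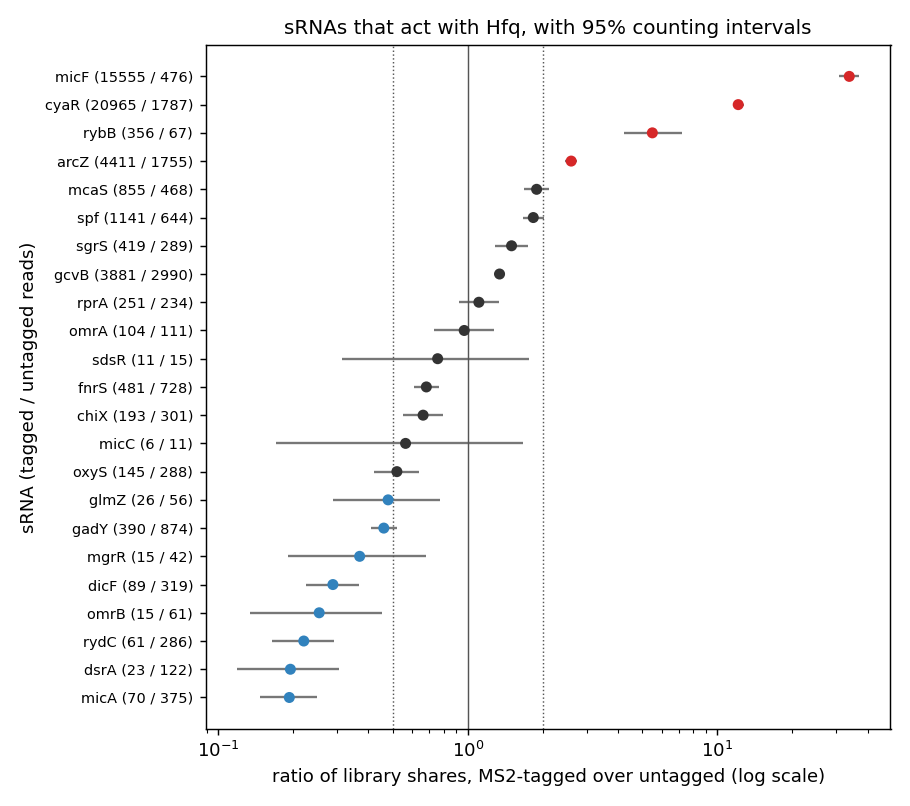
Ratio of library shares, MS2-tagged over untagged, on a log axis for the 23 Hfq sRNAs with at least 10 reads; points are the ratios of the single libraries, bars are 95% counting intervals, and tagged and untagged reads stand beside each name. Red points (MicF, CyaR, RybB, ArcZ) are at least 2-fold higher, blue points at least 2-fold lower; dotted lines mark ratios of 0.5 and 2.

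MicF and CyaR took a larger part of the tagged library, and tRNA and rRNA a smaller one. The listed sRNAs and other small RNAs made up 6.01% (5.96 to 6.06) of the listed reads in the tagged and 1.45% (1.43 to 1.47) in the untagged library. MicF and CyaR held 36520 of the 52237 tagged and 2263 of the 19055 untagged reads of this class. Without them, a comparison chosen after seeing the data, the class made up 1.81% (1.78 to 1.84) and 1.28% (1.26 to 1.296) of the listed reads. As shares of the library total the direction turned, with 0.776% (0.764 to 0.788) in the tagged and 0.802% (0.790 to 0.814) in the untagged library. The rRNA genes made up 18.6% (18.5 to 18.7) and 27.0% (26.9 to 27.1). The tRNA genes outside the bait operon made up 0.284% (0.273 to 0.295) and 0.851% (0.835 to 0.866), and the 3 bait tRNA genes 0.0272% and 0.00988%. All other features made up 75.1% and 70.7%, a direction that turned when rRNA was left out (92.2% and 96.8%) and as shares of the library total (32.2% and 44.4%).

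Most tRNAs were lower with the tagged bait. Of 65 tRNA genes outside the operon with at least 10 reads, 36 were at least 2-fold lower, 3 at least 2-fold higher and 26 neither. Isoleucine tRNA genes of rRNA operons had low ratios, with ileU at 0.0504 (0.0439 to 0.0576) and ileT at 0.0750 (0.0539 to 0.102), and the alanine tRNA gene alaU was at 0.117 (0.0932 to 0.145). The list median was -1.45 (-1.61 to -1.22) on the log2 scale, below that of every random list drawn. Of the 22 rRNA genes, 8 were at least 2-fold lower, none at least 2-fold higher and 14 neither. The genes rrlG and rrlD of large-subunit rRNA had ratios of 0.395 (0.390 to 0.401) and 0.391 (0.386 to 0.397), and rrsD of small-subunit rRNA 0.534 (0.524 to 0.543).

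Of 7 RNAs of other ribonucleoproteins, none was at least 2-fold higher and 2 were at least 2-fold lower. Those were the transfer-messenger RNA ssrA, which rescues stalled ribosomes, at 0.315 (0.297 to 0.334), and ffs, the RNA of the signal recognition particle, at 0.476 (0.388 to 0.583). The RNase P RNA rnpB had a ratio of 0.703 (0.566 to 0.871), ssrS, which binds RNA polymerase, 0.724 (0.651 to 0.805), and csrB 0.612 (0.480 to 0.778). Intervals for csrC (1.23, 0.911 to 1.65) and glmY (0.845, 0.310 to 2.24) included 1. The list median of -0.51 (-0.87 to -0.39) became 0.04 when divided by the listed reads, and 9.88% of random lists had a lower median. Among 10 small antisense RNAs of toxin genes, SokB was higher at 3.42 (1.80 to 6.93), 3 were at least 2-fold lower, RyeA at 0.434 (0.248 to 0.736) among them, and 6 were neither, including SokE at 1.61 (1.09 to 2.39). Their median was -1.27 (-1.69 to -0.43), but 0.68 with a filter of 50 reads.

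The mRNAs regulated through RyhB had a list median of 0.78 (0.47 to 0.82), with 10 of 32 at least 2-fold higher, 3 at least 2-fold lower and 19 neither. The succinate dehydrogenase gene sdhA was at 2.37 (2.19 to 2.55), the aconitase gene acnB at 1.77 (1.65 to 1.90) and the fumarase gene fumA at 0.177 (0.153 to 0.205). Of random lists, 87.7% had a lower median. Among all 5203 features, 26.6% were higher and 14.9% lower by the same rule. Outer membrane protein mRNAs had 5 of 19 members at least 2-fold higher, 3 at least 2-fold lower and 11 neither, with a median of 0.55 (0.21 to 0.63) above that of 69.3% of random lists. Among them ompX had a ratio of 1.48 (1.39 to 1.58), ompC 0.778 (0.745 to 0.813) and the efflux channel gene tolC 0.142 (0.128 to 0.156).

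Ribosomal protein mRNAs were lower as a list. Their median was -0.56 (-0.65 to -0.42), or -0.01 when divided by the listed reads, and 0.07% of random lists had a lower one. Random lists draw features singly, so this share may be too extreme where members lie side by side, as rplC and rplD do. Of 54 genes, 16 were at least 2-fold lower, 8 at least 2-fold higher and 30 neither. The genes rplD and rplC of large-subunit proteins had ratios of 0.0301 (0.0286 to 0.0316) and 0.0271 (0.0252 to 0.0291), with 55266 and 29973 untagged reads. The small-subunit protein gene rpsB was at 0.120 (0.110 to 0.130). Stationary phase mRNAs had a median of -0.26 (-0.38 to -0.14), which 4.80% of random lists lay below and which became 0.29 when divided by the listed reads. Of these 26 genes, 4 were at least 2-fold higher, 4 at least 2-fold lower and 18 neither. The DNA-protecting protein gene dps was at 0.0416 (0.0392 to 0.0442), the acid stress gene hdeA at 2.24 (2.01 to 2.495) and gadC at 0.337 (0.297 to 0.380).

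Arabinose was the inducer for both libraries, and the arabinose genes had a list median near the centre of all features. Their median was 0.21 (0.15 to 0.28), which turned to -0.03 and -0.14 with DESeq2 and edgeR factors, and 51.8% of random lists lay below it. The transporter genes araE and araF had ratios of 1.79 (1.71 to 1.87) and 1.16 (1.11 to 1.21), whereas araJ was at 11.3 (10.4 to 12.3). Of the 9 genes, 2 were at least 2-fold higher, 1 at least 2-fold lower and 6 neither. Among mRNAs of RNA chaperones and RNA decay enzymes, 3 of 18 were at least 2-fold higher, 3 at least 2-fold lower and 12 neither, and the median of 0.13 (-0.09 to 0.30), which turned to -0.11 and -0.22 with DESeq2 and edgeR factors, was above that of 24.7% of random lists. The carbon storage regulator gene csrA was at 10.8 (9.21 to 12.8), the polynucleotide phosphorylase gene pnp at 2.79 (2.498 to 3.13) and the enolase gene eno at 1.29 (1.16 to 1.44).

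Over the 5203 features with at least 10 reads, 676 (12.99%) were at least 4-fold higher and 401 (7.71%) at least 4-fold lower with the tagged bait. Higher features thus made up 62.8% of both together, against 81.5% when dividing by listed reads and 46.2% with edgeR factors. The median log2 ratio of all 5203 features was 0.31, and it moved to 0.86 and -0.04 under those scalings. Of the 1847 features with at least 100 reads, the largest ratios belonged to the rhaD–rhaA region (148 and 2 reads, ratio 76.5, 20.8 to 637.3), the yjiC–iraD region (145 and 2 reads, 74.9, 20.4 to 624.5) and lrhA, the gene of a regulator of flagellar genes (2751 and 40 reads, 71.1, 52.1 to 99.7). The gene ymfI had a ratio of 36.2 (20.9 to 68.5), and MicF ranked 5. The yfiL–yfiR region followed at 33.0 (25.6 to 43.2), alr–tyrB at 31.9 (17.1 to 67.3), yadH–yadI at 30.6 (27.5 to 34.2), yadH at 30.0 (27.0 to 33.5) and guaB–xseA at 30.0 (16.5 to 60.6). CyaR ranked 58 and RybB 185 among these 1847 features.

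The smallest ratios belonged to tff, a small RNA of the rpsB leader, and to the tff–rpsB region next to it. With 1 tagged and 200 untagged reads, tff had a ratio of 0.00517 (0.00013 to 0.0291). The tff–rpsB region, with 1 and 148 reads, was at 0.00698 (0.00018 to 0.0395). The torY–cutC region (9 and 894 reads) was at 0.0104 (0.00474 to 0.0198), and rplD–rplC (37 and 2786 reads) at 0.0137 (0.00964 to 0.0190). The ykgH–betA region had 2 and 147 reads and a ratio of 0.0141 (0.00169 to 0.0517).

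**Figure D2:**
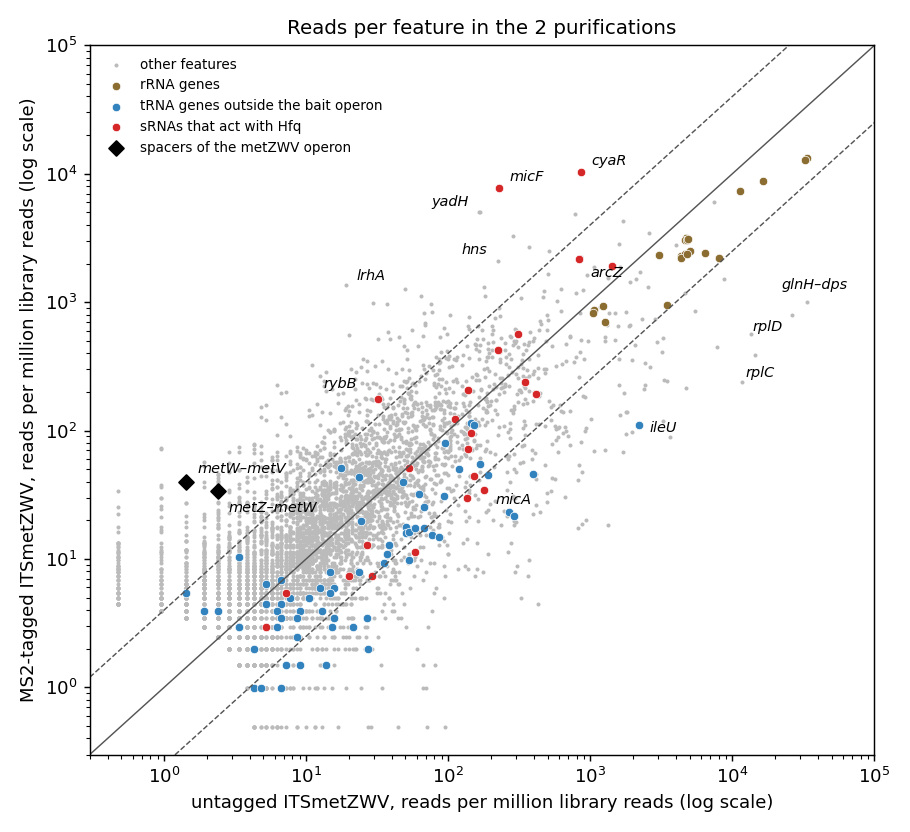
Reads divided by the library total (reads per 1e6, log scales) of the 5203 features with at least 10 reads, untagged library on the horizontal and MS2-tagged library on the vertical axis; each point is 1 feature in the 2 single libraries, the solid line marks equal shares and the dashed lines 4-fold differences. MicF, CyaR and RybB and both spacers lie above the upper dashed line, ileU, rplC, rplD and the glnH–dps region below the lower one; this region and hns, also marked, were chosen after their values were seen.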

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

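No paired analysis was possible because each group has 1 library, and no replicate could be left out. A change of scaling shifts every log2 ratio by 1 constant, from -0.35 (edgeR factors) to 0.55 (listed reads), so ranks, percentiles and differences between RNAs do not depend on it. Of 382 values under alternatives, 194 stayed within the counting interval or tolerance of the reported value (1.5-fold for counts, 5 points for percentiles), 178 moved beyond it and 10 changed sign where the reported counting interval leaves out 0. The genes-only count, the count relative to the median, the shares of the library total and those without MicF and CyaR were chosen after seeing the data.

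MicF's log2 ratio of 5.08 was 5.63 with listed reads (with or without bait tRNA genes), 5.46 without tRNA and rRNA, 4.83 with DESeq2 and 4.73 with edgeR factors. RybB's 2.46 became 3.01 with listed reads, with or without bait tRNA genes. The bait tRNA genes' 0.91 became 1.46 with listed reads, with or without these genes themselves, 1.29 without tRNA and rRNA and 0.56 with edgeR factors. The Hfq list median of -0.55 became 0.0011 with listed reads, 0.0013 without bait tRNA genes, -0.79 with DESeq2 and -0.90 with edgeR factors. The Hfq sRNAs at least 2-fold higher were 7 with either listed-read total instead of 4. Features 4-fold higher and lower (676 and 401) were 1119 and 254 with either listed-read total, 374 and 263 with a pseudocount of 5, and 411 and 229 among genes only; 390 were higher with at least 50 reads. They were 1596 and 934 at 2-fold and 191 and 126 at 10-fold, and all these counts use the ratio without the counting bound. Medians above 0 were found for 4 of the 10 other lists, for 6 with either listed-read total, 5 without tRNA and rRNA or with at least 50 reads, and 2 with DESeq2 or edgeR factors. Besides the Hfq list with either listed-read total, list medians with an interval without 0 that changed sign were those of other ribonucleoprotein RNAs (0.0438 with listed reads, 0.0440 without bait tRNA genes), stationary phase mRNAs (0.2903, 0.2905 and, without tRNA and rRNA, 0.12), arabinose mRNAs (-0.0303 with DESeq2, -0.1394 with edgeR factors) and toxin antisense RNAs (0.68 with at least 50 reads). Where the reported interval includes 0, signs also changed for RNA chaperone and RNA decay mRNAs (0.13, to -0.11 with DESeq2 and -0.22 with edgeR factors) and for metZ (0.08, to -0.16 and -0.27). These sign changes follow from the constant shifts, except that of toxin antisense RNAs, where fewer RNAs were left.

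Without rRNA, the shares of listed reads in the tagged and untagged library became 0.0334% and 0.0135% for bait tRNA genes, 0.349% and 1.17% for other tRNA genes, 7.39% and 1.99% for small RNAs, and 92.2% and 96.8% for all other features. As shares of the library total they were 0.0117% and 0.00621% for bait tRNA genes, 0.122% and 0.535% for other tRNA genes, 7.97% and 17.0% for rRNA, 2.58% and 0.910% for small RNAs, and 32.2% and 44.4% for the rest. Without MicF and CyaR, small RNAs made up 1.81% and 1.28% of the listed reads, and 0.776% and 0.802% of the library total. Depth limits RyhB (7 reads) and the spacers (157 reads in all), and counting intervals leave out the spread between purifications.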

Other observations

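The tests of Hfq carry-over, scaling, shared reads, differences between single libraries, read piles and sRNA targets, and the limit for a gain of neighbouring genes, were chosen after the result, or part of it, was seen, as were the features named here; the tests of neighbouring genes' ratios themselves were chosen before their medians were known, but after a few single neighbours had been seen.

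Several intergenic regions and mRNAs outside the lists carried many reads with the tagged bait. The nucleoid protein gene hns and the hns–tdk region beside it had ratios of 9.42 (8.56 to 10.4) and 9.33 (7.61 to 11.6). The glnL–glnA region, beside the glutamine synthetase gene, had 9812 tagged and 1642 untagged reads, a ratio of 6.17 (5.86 to 6.51). The hfq–hflX region was at 2.502 (2.41 to 2.60) with 8679 tagged reads, while hfq itself, encoding the chaperone, was at 0.909 (0.697 to 1.18). The rhtA–ompX region in front of the outer membrane protein gene ompX, whose mRNA is a known target of CyaR, was at 10.0 (8.43 to 11.97), against 1.48 (1.39 to 1.58) for ompX. In the other direction, dps and the regions on either side were low together, with glnH–dps at 0.0300 (0.0286 to 0.0313) from 69955 untagged reads and dps–rhtA at 0.0431 (0.0271 to 0.0654).

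MicF, CyaR and RybB were higher with the tagged bait by 5.08, 3.60 and 2.46 on the log2 scale. A carry-over of all Hfq-bound sRNAs alike would raise the others too. The median of the 20 other measured Hfq sRNAs was -0.71 (-0.95 to -0.49). Setting aside the members with the highest ratios lowers this median, and that of the whole list was -0.55, or 0.0011 with listed reads. Of the others, ArcZ, McaS, spf, SgrS and GcvB had ratios of 2.60, 1.89, 1.83, 1.498 and 1.34 with lower bounds above 1, whereas 8 were at least 2-fold lower. Carry-over of only some Hfq sRNAs therefore stays open. The lowest value of MicF, CyaR or RybB over 7 scalings was 2.105 (RybB, lower bound 1.72), which argues against scaling as the source. None of the 5 listed intergenic regions beside them held more than 1.69% of an sRNA's tagged reads. This argues against reads shared with those regions only. Neighbouring and overlapping genes were not checked, so reads shared with a gene, as may hold for ArcZ and arcB, stay open. A chance difference between 2 single purifications stays open: among features with at least 100 reads, 0.271% had a ratio as high as MicF, 3.14% as high as CyaR and 10.0% as high as RybB. Binding of these sRNAs to the spacers is a hypothesis that 1 library per group cannot separate from it.

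A group of 36 features with at least 1000 untagged reads was at least 10-fold lower with the tagged bait and held 24.8% of the listed untagged reads. Loss of a whole neighbourhood would lower nearby genes. Members of the set and intergenic regions were not counted as neighbours, so low features lying side by side, such as rplC and rplD, do not enter. Genes without at least 1 read in both libraries, or with fewer than 10 reads in all, do not enter either. The complete loss of a gene could therefore not be seen. Among genes outside the set, the 72 nearest to its 24 protein-coding members had a median log2 ratio of -0.32 (-0.87 to 0.11). The median of all genes with at least 10 reads, 0.34, lies above this interval. These neighbours were thus lower than a typical gene, and a partial loss stays open. For genes read in both libraries, the values argue against loss of a whole neighbourhood beyond the set. Exceptions were the genes nearest to rplC, rplD and rplW (-2.26), rimP and argG (-2.25), dmsD (-2.13), yhhW (-1.63), fadD (-1.39) and atpG (-1.37), where such a loss stays open. Reads piled up at single places of the untagged library may be the source, since these genes stood above their neighbours in reads per length by a median log2 of 4.25 (3.68 to 4.89) there. The 26 genes with at least 1000 untagged reads and a ratio within 2-fold stood at 3.68 (1.91 to 4.64), an interval that overlaps. They were not matched on reads beyond this minimum. Read piles therefore cannot be told apart from how abundant genes look in these libraries.

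In the opposite direction, 20 features with at least 1000 tagged reads were at least 10-fold higher. Members of the set, intergenic regions and genes without at least 1 read in both libraries were again not counted as neighbours. The 42 nearest other genes of the 12 protein-coding members, lrhA, yadH, gcd and wecA among them, had a median log2 ratio of 0.49 (0.18 to 1.01). Both the median and its upper bound lie below the 2 that a gain of whole neighbourhoods would need. For genes outside the set that had reads in both libraries, this argues against such a gain. The limit first written was a median below 1, which was met, though the upper bound lies just above 1. Neighbours of gcd (1.80), yjiN (1.49), lrhA (1.11) and wecA (1.01) were highest, and there a gain stays open. The 12 protein-coding members stood above their neighbours by 4.84 (3.59 to 7.35) in the tagged library. However, 31 genes with at least 1000 tagged reads and a ratio within 2-fold, not matched further on reads, stood at 3.42 (2.08 to 4.35). Local read piles stay open.

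Co-purification of the mRNAs that these sRNAs regulate was tested on features naming 21 known targets of CyaR, MicF and RybB. The 47 features had a median log2 ratio of 0.0473, above that of 13.01% of random sets and under their 95th percentile of 0.78. Members went both ways, so a gain of targets is neither shown nor excluded. The 10 features of MicF targets had a median of 0.50 (percentile 54.2, 4 at least 2-fold higher, 0 lower) and the 11 of CyaR targets 0.35 (percentile 49.2, 2 higher, 0 lower). The 29 of RybB targets, at -0.01 (percentile 16.8), had 4 higher and 6 lower members. Counts of higher and lower features in this paragraph also need a counting bound beyond 1, as for listed RNAs. At least 2-fold higher were 8 features (17.0%, against 26.6% of all 5203), among them rhtA–ompX, the cpxR–cpxP region at 9.11 (5.42 to 16.4) and the yajD–tsx region at 6.16 (5.52 to 6.88). At least 2-fold lower were 6 (12.8%, against 14.9%), among them the ompW–yciE region at 0.0646 (0.0455 to 0.0893) and the matP–ompA region at 0.222 (0.162 to 0.299). Such regions also adjoin another gene, so their reads need not come from the target. The target genes themselves were at 1.48 for ompX, 0.832 (0.492 to 1.40) for cpxR and 3.28 (2.77 to 3.91) for tsx. For ompW the ratio was 1.82 (1.63 to 2.04) and for ompA 0.481 (0.4425 to 0.523).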
